A study of Mus musculus with 16 samples.

How the data were processed

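The 16 libraries were mRNA sequencing libraries of E14 mouse embryonic stem cells of 1 genotype, a Ddx10 degron line with Tir1, in 8 groups of 2. Per the labels, cells grew on gelatin in medium with serum, 1000 U/mL LIF, CHIR99021 and PD0325901, and indole-3-acetic acid was added to 500 µM to induce DDX10 degradation. Also per the labels, mRNA was purified from total RNA and libraries were made with a VAHTS Universal V6 kit. Times, doses and replicate numbers were taken from the labels, and every library entered the fit.

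The deposited values are a signal in the unit of normalized read counts: the authors divided gene-level counts by a scaling factor per library before the table was deposited. That statement rests on the name of the table and on its values, which are not whole numbers and have similar quartiles in all libraries. Per the labels, the authors used Trim Galore, STAR, RSEM and DESeq2 with the mouse build mm10, which is the same assembly as GRCm38. Versions, the role of each tool, the gene annotation and the filter that left 14552 genes are not given in the sources used here. For 1884 genes with 1 annotated transcript, 71.2% to 98.9% of low values per library lay within 0.1 of a whole multiple of 1 step, tested up to 20 steps, against 35.7% to 45.4% for other genes. Whole reads could therefore not be recovered for all genes. The value of 1 read was between 0.892 and 1.24, so a library held roughly 13.6 M to 17.5 M reads in genes, and the 10 highest genes held 4.90% to 5.72% of a library. The median standard error of a log2 change was 0.158. Gene positions are from GENCODE M21 on GRCm38, in which 14467 of the gene identifiers were found and 85 were not.

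Values were used as deposited, as log2(value + 1), which understates the fold change of genes with low values. Genes with a mean of at least 10 over the 16 libraries were tested, 13355 in all. All libraries entered 1 linear model with a mean per group in limma 3.58.1 under R 4.3.3, with an intensity trend in the empirical Bayes step and 8 residual degrees of freedom. Each of the 6 times under auxin and the withdrawal group was compared with untreated, and withdrawal was also compared with 2 days of auxin. P-values were adjusted by Benjamini-Hochberg within each comparison, and genes with an adjusted p below 0.05 are called higher or lower. An F-test over the 6 times asked for any change under auxin. The median log2 change of all genes lay between -0.012 and 0.023 in every comparison.

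The code was tested on simulated data made from the spread of these libraries, in a comparison of 2 days with untreated over 13355 genes. Of genes changed by a log2 value of 0.5, 1 and 2, it called 40.9%, 70.1% and 89.6%, and of 143 calls 9 were of unchanged genes. The requirement on recovery at a log2 change of 2 had first been set at 90%, and the simulation missed it. It was then lowered to 75%, after that failure, so it is not an independent bar. The 7 genes missed had means between 12.5 and 40.1.

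Gene lists were written from general knowledge before the data were examined, as were the comparisons, the test, the thresholds and the rule for naming genes. Of 25 lists, 24 had enough genes to test, and the list of mitochondrially encoded genes was not analysed here because none of its genes is among those in the table. The ribosomal protein list had 7 of 78 genes, so it says little about that class as a whole. Each list was tested in each of the 8 comparisons with limma camera at a preset correlation between genes of 0.01, and p-values were adjusted over these 192 tests. Of 87 calls, 8 held when camera estimated the correlation between genes from the data, and 81 also passed fry, a rotation test. "Adjusted over the list alone" means Benjamini-Hochberg over the members of the list.

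Genes were named by a rule: Ddx10, Trp53, Mdm2, Cdkn1a, Pou5f1, Nanog, Sox2, Zfp42, Klf4, Esrrb, Dppa3, Zscan4c, Zscan4d and Duxf3 throughout, of which Duxf3 was not analysed here. To these were added, per comparison, called genes with the largest log2 changes in either direction, a mean of at least 50 over the groups compared, no predicted-gene name and no overlap between the 2 groups. That part allowed 10 in each direction at 2 days, 5 at 1 day and in the withdrawal comparisons, and 3 at earlier times. For each list up to 4 members with the smallest p were added. Not every gene the rule allows is printed, and some results are not reported here. Zscan4, Usp17l and similar genes exist as near-identical copies, so how their reads were divided between copies is uncertain.

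Alternatives chosen before the data were examined were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, rescaling by trimmed means of M values (written out for this work) and by upper quartiles, replicate as a block, a fit of the 2 compared groups alone, leaving out each library in turn, an estimated correlation for camera, and fry. Alternatives chosen after the data were seen were library weights, removal of a trend over transcript length and GC content, a fit of the libraries outside 2 to 12 h, the 2 h libraries as the baseline for 4, 6 and 12 h with and without that trend, and 1 untreated library for each of a pair of comparisons. When a library was left out, the group's other library was assumed to vary as the rest do. Overlaps between comparisons that share untreated libraries were set against 100 simulations of unchanged groups, drawn with the pooled spread. They were also set against fits in which the pair shared no untreated library, with the spread taken from the other 7 groups.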

Results

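Gene expression was measured by mRNA sequencing in E14 mouse embryonic stem cells. The cells carried an auxin-inducible degron on Ddx10 and expressed Tir1, the plant F-box protein through which auxin directs a tagged protein to degradation. DDX10 is a DEAD-box RNA helicase, and the title of the series links it to pluripotency and to the processing of 18S rRNA, the RNA of the small ribosomal subunit. Cells were kept in medium with serum, LIF and inhibitors of GSK3 and MEK. They were collected untreated, after 2, 4, 6 and 12 h, 1 day and 2 days in 500 µM indole-3-acetic acid (auxin), and after 2 days in auxin followed by 2 days without it, called withdrawal here. Each of the 8 groups had 2 libraries, which gave 16 libraries in all. The design asks how transcripts change with time under auxin and how far they return after withdrawal. Auxin-treated cells without the tag were not analysed here, so an effect of auxin itself and an effect of DDX10 loss cannot be separated.

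The table of normalized counts held 14552 genes, of which 13355 had a mean of at least 10 and were tested. Normalized totals were similar across libraries, and between 14408 and 14494 genes had a value above 0. From the step between low values, each library was estimated to hold between 13.6 M and 17.5 M reads on these genes. At this depth the median standard error of a log2 change between groups was 0.16. Gene values below are means of normalized counts ± SD with n = 2, log2 changes are on the scale of log2(value + 1), and adjusted p-values are from limma with Benjamini-Hochberg adjustment within a comparison. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

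Replicates differed by more than counting noise in every group, with a chi-square per degree of freedom of 4.92 to 27.8, so no pair of libraries was treated as 1 sample. The spread was uneven. The log2 difference between replicates had an SD over genes of 0.62 in untreated cells, with 1090 genes at least 2-fold apart. The SD was 0.53 at 1 day (774 genes) and 0.37 to 0.41 in the other 6 groups (342 to 493). P-values against untreated use the pooled spread and may be too small. The first principal component held 40.6% of the variance and the second 19.6%.

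**Figure D1:**
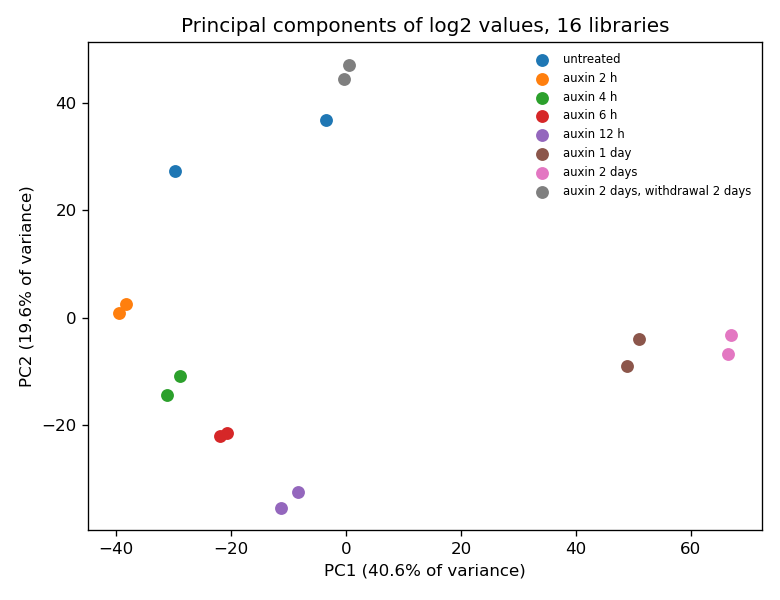
Principal components of the log2 values of all 16 libraries, with the first component (40.6% of variance) on the x axis and the second (19.6%) on the y axis, and 1 point per library coloured by group. Libraries of a group lie near each other except the untreated ones, each of which lies nearer to a library of another group, and the withdrawal libraries lie nearer to the untreated libraries than the 2 day libraries do.

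A split of the libraries ran across the time course. For 1015 genes, 424 higher and 591 lower, all 8 libraries of 2, 4, 6 and 12 h lay beyond all 8 libraries of the other 4 groups. That is the most for any of the 35 ways to divide the 8 groups into 4 and 4. By chance 16 independent libraries would part in this way at 0.0155% of genes, or 2.08 genes. Libraries of a group are not independent of each other, so this value is too low to judge the split by. The next division, with untreated, 2 h, 4 h and withdrawal on one side, had 691 such genes. Lars2, a mitochondrial leucyl-tRNA synthetase, was at 620 to 791 in the libraries of 2 to 12 h and at 2810.5 to 18293 in the others. Further genes that show the size of the split were chosen after their values were seen. The respiratory chain genes Cox8a and Ndufa1 were at 1737 to 2168 and 192 to 252 in the libraries of 2 to 12 h, against 3644 to 4736 and 468 to 922 in the others. Mapre1, a microtubule end-binding protein gene, was at 5829 to 8824 against 2574 to 3276. Across genes, which are not independent replicates, the log2 change against untreated had a Spearman correlation with transcript length of 0.22 at 2 h, 0.21 at 4 h, 0.23 at 6 h and 0.24 at 12 h. The same correlation was 0.06 at 1 day, 0.09 at 2 days and -0.01 after withdrawal, and within the libraries of 2 to 12 h it was -0.03, 0.02 and 0.09 for 4, 6 and 12 h against 2 h. With GC content the correlation was -0.22 at 2 h and between -0.04 and -0.02 at 4 to 12 h, and 0.28, 0.24 and 0.13 for 4, 6 and 12 h against 2 h, so the 2 h baseline has a trend of its own. Over all tested genes the division was less sharp: untreated replicate 2 had a Pearson correlation of 0.975 with 2 h replicate 1 and 0.973 with untreated replicate 1. The labels name no library batch, so a batch of the 2 to 12 h libraries and the early times cannot be told apart in comparisons with untreated cells. Values against 2 h are therefore printed beside many of the results for 4, 6 and 12 h, as comparisons chosen after the data were seen.

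Ddx10 mRNA, from the targeted gene (ENSMUSG00000053289, chromosome 9, 53098635 to 53248053, minus strand, GRCm38), was present in every library. It was at 1433 and 1509 in the untreated libraries, 1847 and 2046 at 2 h, 1886 and 1855 at 4 h, 1676 and 1675 at 6 h, and 1312 and 1305 at 12 h. It was at 1160 and 889 at 1 day, 997 and 1040 at 2 days, and 1695 and 1498 after withdrawal. Against untreated, Ddx10 mRNA rose at 2 h (log2 change 0.40, limma adjusted p = 0.025) and 4 h (0.35, adjusted p = 0.039), and fell at 1 day (-0.53, adjusted p = 0.0018) and 2 days (-0.53, adjusted p = 0.0013). Leaving out any 1 of the 4 libraries ended the call at 4 h (adjusted p of 0.061 to 0.17), and leaving out untreated replicate 1 (0.089), 2 h replicate 1 (0.051) or 2 h replicate 2 (0.19) ended it at 2 h. Without 1 day replicate 2 the change at 1 day was -0.34 and still called. The degron acts on the protein, so these values do not measure how much DDX10 was removed.

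After 2 h of auxin the clearest rise was in targets of the aryl hydrocarbon receptor, a ligand-activated transcription factor that binds indoles. Cyp1b1, a cytochrome P450 gene, rose from 13.9 ± 0.407 to 213 ± 6.79, and Cyp1a1, the classical target of the receptor, from 62.1 ± 17.4 to 371 ± 61.8. Insig1, a sterol-responsive gene, rose to 1921 ± 24.8 from 1359 ± 77.5. Transcripts that fell included Chac1, a glutathione-degrading enzyme gene induced by ATF4 (24.2 ± 3.46 against 217 ± 139.8), Lefty2, a Nodal antagonist (242 ± 10.9 against 1104 ± 382), and Spry4, a feedback inhibitor of FGF signalling (183 ± 13.3 against 666 ± 116). Pou5f1, which encodes the pluripotency factor OCT4, fell from 22755 ± 588 to 17017 ± 861 (log2 change -0.42, limma adjusted p = 0.0028).

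Of 9 tested aryl hydrocarbon receptor targets, 3 rose at 2 h and 6 did not pass, or 4 and 5 adjusted over the list alone. The list median was 0.46, above 0 in both 2 h libraries, with a camera adjusted p of 0.00035 and an adjusted p = 0.055 with an estimated correlation. The third member to rise was Nfe2l2, a regulator of the antioxidant response, at 2308 ± 22.6 against 1849.7 ± 47.0. Its call ended without 2 h replicate 1 (limma adjusted p = 0.065), without replicate 2 (0.10), with the 2 groups fitted alone (0.087) and with the length and GC trend removed (0.064). Among 33 targets of ATF4, the transcription factor of the integrated stress response, 6 fell, or 7 adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.0016, and adjusted p = 0.28 with an estimated correlation). That call ended without untreated replicate 2, where the median was -0.10 (adjusted p = 0.18), and with the length and GC trend removed (adjusted p = 0.18). Without 2 h replicate 1 the median was -0.24.

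The p53 target list was not called at 2 h: its median was 0.06, its mean -0.05 and the test pointed up (adjusted p = 0.96), with 4 of 39 members higher and 4 lower, and the same numbers adjusted over the list alone. Within it Mdm2, the ubiquitin ligase gene that p53 induces, rose from 2454 ± 29.5 to 3247 ± 15.3 (log2 change 0.40, limma adjusted p = 0.0077, or 0.062 without 2 h replicate 2). The cell death genes Pmaip1 and Bax fell to 110.5 ± 10.2 and 1846 ± 100.3 from 290.3 ± 114 and 2848 ± 177. The Pmaip1 call ended with the 2 groups fitted alone (limma adjusted p = 0.071). Cdkn1a, a cell cycle inhibitor gene and p53 target, was at 1726 ± 154 against 1530.1 ± 10.1, which did not pass.

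In total, 902 genes were higher and 1128 lower at 2 h than in untreated cells, 104 and 185 of them by at least 2-fold, while 4078 genes had an unadjusted p below 0.05. With 2 h replicate 1 left out the counts were 385 and 602, with replicate 2 left out 166 and 335, and with the untreated and 2 h libraries fitted alone 138 and 270. Vwf, Serpina3m and Lars2, also among the largest changes by the naming rule, rested on uneven replicates. Untreated Serpina3m was at 141 ± 177 and untreated Lars2 at 9252 ± 9109. The log2 change of Lars2 at 2 h went from -3.16 to -1.92 without untreated replicate 1. The Lars2 call ended with the 2 groups fitted alone (limma adjusted p = 0.074). The Vwf call ended without untreated replicate 2 (limma adjusted p = 0.16), and the Serpina3m call without untreated replicate 1 (0.072).

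After 4 h of auxin p53 targets rose together. Mdm2 (chromosome 10, 117688875 to 117710758) reached 5903 ± 209 from 2454 ± 29.5, Cdkn1a (chromosome 17, 29090976 to 29100727) 2732 ± 5.17 from 1530.1 ± 10.1, and Ccng1, a cyclin G gene, 9960.3 ± 211 from 4669 ± 114. Plk2, a stress-responsive kinase gene, rose from 491 ± 184 to 2137 ± 127, and Btg2, an antiproliferative gene, from 529 ± 176 to 1859 ± 168. Of the 39 p53 targets tested, 22 rose and 1 fell, with the same numbers adjusted over the list alone. The list median was 0.55 and above 0 in both 4 h libraries (camera adjusted p = 3.1e-12, and adjusted p = 0.065 with an estimated correlation). Against 2 h the median was 0.60 with 26 members higher (adjusted p = 5.3e-27, and adjusted p = 0.022 with an estimated correlation), and Mdm2 rose by a log2 change of 0.86.

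Sterol synthesis genes also rose at 4 h. Hmgcs1, the first committed enzyme gene of the mevalonate pathway, rose from 3622 ± 298 to 6073 ± 108, and Cyp51, a lanosterol demethylase gene, from 1278 ± 12.9 to 1873 ± 14.8. Of 25 members 11 rose and 1 fell, or 13 and 1 adjusted over the list alone. The sterol median was 0.29 (camera adjusted p = 8.1e-06, and adjusted p = 0.031 with an estimated correlation). Against 2 h it was also 0.29 (adjusted p = 2.2e-09, and adjusted p = 0.022 with an estimated correlation). Cyp1a1 reached 980.5 ± 9.89 and Cyp1b1 215 ± 15.6. Of the 9 receptor targets 5 rose, with the same number adjusted over the list alone (median 0.24, or 0.41 without untreated replicate 2; camera adjusted p = 0.00091, and adjusted p = 0.071 with an estimated correlation), but against 2 h the receptor list was not called (median 0.02, adjusted p = 0.75). Neurod1, a neuronal transcription factor gene, rose from 22.2 ± 1.61 to 129.8 ± 13.2 (limma adjusted p = 2.7e-05).

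Targets of ATF4 fell at 4 h. Mthfd2, a mitochondrial folate enzyme gene, was at 1104 ± 34.9 against 2155 ± 405 and Slc7a3, an arginine transporter gene, at 2627 ± 122 against 4598 ± 748. Of 33 members 18 fell and 2 rose, or 20 and 2 adjusted over the list alone (median -0.35, camera adjusted p = 2.2e-06, and adjusted p = 0.14 with an estimated correlation). Against 2 h the ATF4 median was -0.20 (adjusted p = 0.00013, and adjusted p = 0.12 with an estimated correlation). The members that rose were Ddit4 (955 ± 1.49 against 360.5 ± 28.5) and Sesn2 (5700.5 ± 118 against 3583 ± 324), both inhibitors of mTORC1 signalling that p53 also induces. Among pluripotency genes Utf1 fell from 4752 ± 370.2 to 2606 ± 121, Zfp42 (REX1) from 11639 ± 659.7 to 9040.3 ± 147 and Pou5f1 to 16076 ± 762. Of 32 such genes 13 fell and 2 rose, with the same numbers adjusted over the list alone. Their median was -0.10 (camera adjusted p = 0.014, and adjusted p = 0.38 with an estimated correlation). The call ended without untreated replicate 1 (median -0.06, adjusted p = 0.64). Without untreated replicate 2 the median was -0.31, with the length and GC trend removed -0.06, and against 2 h it was -0.18 (adjusted p = 1.2e-08, and adjusted p = 0.022 with an estimated correlation).

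In the comparison of 4 h with untreated cells 1183 genes were higher and 1365 lower, of which 223 and 185 differed by at least 2-fold. Without 4 h replicate 1 the counts were 421 and 505, without replicate 2 they were 565 and 733, and with the untreated and 4 h libraries fitted alone 337 and 394. Against 2 h, 642 genes were higher and 486 lower at 4 h, of which 360 and 128 were also called against untreated in the same direction and 23 in the opposite direction.

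At 6 h p53 targets were above untreated cells and ATF4 targets below. Mdm2 was at 5276 ± 82.3, Cdkn1a at 2795 ± 58.3, Ccng1 at 11132 ± 222 and Plk2 at 2238 ± 13.9, and 26 p53 targets rose and 1 fell, with the same numbers adjusted over the list alone. The median was 0.63 (camera adjusted p = 5.8e-15, and adjusted p = 0.0501 with an estimated correlation) and 0.70 against 2 h. In the ATF4 list 22 of 33 fell and 2 rose, or 23 and 2 adjusted over the list alone, with a median of -0.51 (camera adjusted p = 6.3e-10, and adjusted p = 0.085 with an estimated correlation) and of -0.37 against 2 h (adjusted p = 4.2e-08, and adjusted p = 0.065 with an estimated correlation). Its members Aldh18a1, a proline synthesis gene, and Mthfd2 fell to 777 ± 5.12 and 883 ± 50.6 from 1945 ± 221 and 2155 ± 405, while Ddit4 rose to 1160.4 ± 18.0.

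Of 62 genes for making the small (40S) ribosomal subunit, 19 fell and 5 rose at 6 h, or 21 and 6 adjusted over the list alone. Dimt1, an 18S rRNA methyltransferase gene, was at 607 ± 4.86 against 900.4 ± 9.78, Utp3 at 1628 ± 121 against 2348 ± 116 and Emg1, another 18S rRNA modifying enzyme gene, at 2087 ± 5.38 against 2907 ± 188. The list median was -0.16 (camera adjusted p = 0.0092, and adjusted p = 0.54 with an estimated correlation). Leaving out untreated replicate 1 ended the call (median -0.09, adjusted p = 0.12). With the length and GC trend removed the median was -0.10, and against 2 h the median was -0.15 (adjusted p = 4.5e-06, and adjusted p = 0.055 with an estimated correlation). For the 56 large-subunit genes the median was -0.15, with 21 lower and 2 higher over all genes and adjusted over the list alone (camera adjusted p = 0.00077, and adjusted p = 0.33 with an estimated correlation). It was -0.07 without untreated replicate 1 and -0.16 against 2 h. Pluripotency genes had a median of -0.21 with 13 lower and 2 higher, or 13 and 3 adjusted over the list alone (camera adjusted p = 0.0019, and adjusted p = 0.30 with an estimated correlation). That call ended without untreated replicate 1 (median -0.07, adjusted p = 0.24), and against 2 h the median was -0.21 (adjusted p = 7.2e-09, and adjusted p = 0.022 with an estimated correlation). Utf1 was at 2145 ± 84.9, Zfp42 at 8275 ± 186 and Pou5f1 at 15013 ± 337, all lower than untreated. The receptor targets Cyp1a1 and Cyp1b1 were at 659 ± 16 and 203 ± 7.33. Of the 9 list members 3 rose, with the same number adjusted over the list alone (median 0.35, or 0.60 without untreated replicate 1; camera adjusted p = 0.0013, and adjusted p = 0.071 with an estimated correlation). Compared with 2 h the receptor list was not called (median -0.03, adjusted p = 0.80).

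In all, 1462 genes were higher and 1791 lower at 6 h, 371 and 240 of them by at least 2-fold. Leaving out 6 h replicate 1 gave 654 and 953, leaving out replicate 2 gave 687 and 1002, and fitting the untreated and 6 h libraries alone gave 587 and 824. Compared with 2 h, 1164 genes were higher and 1336 lower, with 636 and 499 called in the same direction against untreated and 36 in the opposite direction. Apbb2, the largest rise after the receptor targets, was at 3050.2 ± 3663 in the 6 h libraries, and its call ended without 6 h replicate 1 (limma adjusted p = 0.21) or untreated replicate 2 (0.072).

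By 12 h several pluripotency genes were well below untreated cells while p53 targets stayed high. Utf1 fell to 1066 ± 61.7 from 4752 ± 370.2, Nr0b1 (DAX1) to 599.5 ± 29.4 from 2279.8 ± 67.5, and Pou5f1 to 13543 ± 5.55 from 22755 ± 588, the lowest Pou5f1 mean of the 8 groups. Trp53inp1, a p53-induced autophagy and cell death gene, rose from 2530.0 ± 225 to 8481 ± 307, Ccng1 to 11738 ± 447 and Cdkn1a to 3873 ± 136. Neurod1 reached 202 ± 31.8, the annexin gene Anxa8 146 ± 21.2 from 18.0 ± 9.66, and the carboxypeptidase gene Cpz 152 ± 26.5 from 19.9 ± 0.525.

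Small-subunit biogenesis genes fell at 12 h, with 39 of 62 lower and 3 higher, or 41 and 3 adjusted over the list alone. Lyar, a nucleolar protein gene, went to 1986 ± 52.5 from 3678 ± 53.3, Utp3 to 1342 ± 62.0 and Emg1 to 1738 ± 67.1. Their median was -0.36 (camera adjusted p = 8.8e-10, and adjusted p = 0.20 with an estimated correlation), and against 2 h it was also -0.36 with 51 lower (adjusted p = 3.8e-14, and adjusted p = 0.022 with an estimated correlation). Large-subunit genes had a median of -0.33 and 34 of 56 fell, or 38 adjusted over the list alone (camera adjusted p = 3.1e-10, and adjusted p = 0.13 with an estimated correlation), and against 2 h the median was -0.37 (adjusted p = 5.1e-14, and adjusted p = 0.022 with an estimated correlation). Npm1, a nucleolar protein gene, was at 32499 ± 224 against 54085 ± 1629 and Gnl3 at 2991 ± 52.0 against 4788 ± 311. In the ATF4 list 25 of 33 fell and 2 rose, or 26 and 2 adjusted over the list alone (median -0.91, camera adjusted p = 2.9e-11, and adjusted p = 0.071 with an estimated correlation), with a median of -0.79 against 2 h (adjusted p = 8.4e-08, and adjusted p = 0.067 with an estimated correlation). The serine synthesis gene Psat1 was at 2815 ± 26.3 against 8696 ± 523. For the p53 targets 28 rose and 2 fell, or 29 and 2 adjusted over the list alone (median 0.71, camera adjusted p = 1.1e-13, and adjusted p = 0.054 with an estimated correlation), and the median was 0.87 against 2 h.

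Of 32 pluripotency genes 13 fell and 5 rose at 12 h, with the same numbers adjusted over the list alone, and the median was -0.24 (camera adjusted p = 0.034, and adjusted p = 0.45 with an estimated correlation). The call ended with a mean of at least 50 required (adjusted p = 0.074). Without untreated replicate 1 the median was 0.02 (adjusted p = 0.51), without untreated replicate 2 it was -0.38, and against 2 h it was -0.29 (adjusted p = 0.00027, and adjusted p = 0.059 with an estimated correlation). Cyp1a1 was at 228 ± 20.3 and Cyp1b1 at 56.3 ± 0.196, both still above untreated, with log2 changes of -0.69 and -1.90 against 2 h. The receptor target list as a whole was not called (median 0.26, camera adjusted p = 0.080), nor was it against 2 h (median -0.23, adjusted p = 0.095). Trp53 itself fell to 7377 ± 265 from 8800.2 ± 605 (log2 change -0.25, limma adjusted p = 0.0078; 0.061 without untreated replicate 1, 0.076 without 12 h replicate 1 and 0.075 with the 2 groups fitted alone).

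The 12 h comparison had 1976 genes higher and 2446 lower, 560 and 445 of them by at least 2-fold. The higher count was 1095 without 12 h replicate 1, 1212 without replicate 2 and 1183 with the untreated and 12 h libraries fitted alone. Against 2 h, 2158 genes were higher and 2829 lower at 12 h, of which 1179 and 1521 were called in the same direction against untreated and 59 in the opposite direction.

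Several lists were called lower than untreated at times on the 2 to 12 h side of the library split. The 7 cytosolic ribosomal protein genes tested had medians of -0.44, -0.38, -0.42 and -0.59 at 2, 4, 6 and 12 h, with 4, 4, 4 and 6 lower, or 4, 4, 4 and 7 adjusted over the list alone. These lists were called (camera adjusted p = 0.00091, 0.0022, 0.0020 and 0.00022, and adjusted p = 0.34, 0.38, 0.38 and 0.30 with an estimated correlation). Without untreated replicate 1 the medians were -0.29 at 2 h, -0.23 at 4 h (adjusted p = 0.057, no longer called) and -0.27 at 6 h. With the length and GC trend removed, an alternative chosen after the data were seen, they were -0.17, -0.24, -0.25 and -0.37, and the calls at 2 h (adjusted p = 0.16) and 6 h (0.055) ended. Rplp1, a ribosomal stalk protein gene, was at 11559.9 ± 639.7 at 2 h and 10778 ± 672 at 12 h against 23737 ± 2621 untreated. Against 2 h the list was lower at 12 h (median -0.18, 5 lower, adjusted p = 0.020, and adjusted p = 0.33 with an estimated correlation). The list had a median of 0.13 at 1 day (adjusted p = 0.48). At 2 days it had a median of -0.09 with 2 members higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.95). Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, had medians of -1.10, -1.04 and -1.08 at 2, 6 and 12 h, with 3, 4 and 6 of 13 lower, or 5, 4 and 6 adjusted over the list alone. Its medians at 1 and 2 days, -0.47 and -0.28, were not called (adjusted p = 0.27 and 0.75), and the difference from the early times was not tested. The histone list was called at 2, 6 and 12 h (camera adjusted p = 0.0092, 0.029 and 0.018, and adjusted p = 0.14, 0.19 and 0.16 with an estimated correlation). The histone calls ended without untreated replicate 1 at 6 h (adjusted p = 0.097) and 12 h (0.058) and without 6 h replicate 2 (0.065), and at 6 h also with library weights (0.061) and with the length and GC trend removed (0.070). Genes of the 2-cell stage had medians of -0.72, -0.59 and -0.68 at 4, 6 and 12 h, with 3, 2 and 5 of 22 lower, and 2 and 4 adjusted over the list alone at 4 and 12 h. This list was called too (camera adjusted p = 0.0042, 0.029 and 0.020, and adjusted p = 0.54, 0.61 and 0.61 with an estimated correlation). Without untreated replicate 1 these medians were -0.10, 0.016 and -0.0093 and no call was left (adjusted p of 0.83 to 0.84), and with pseudocount 5 the 4 h median was -0.47. Without untreated replicate 2 they were -1.39, -1.17 and -1.59, and without 6 h replicate 1 the 6 h call ended (adjusted p = 0.060). The calls also ended with fry (adjusted p = 0.11, 0.17 and 0.088), at 6 h with the 2 groups fitted alone (0.058), and at 6 and 12 h with a mean of at least 50 required (0.071 each). Against 2 h the 2-cell list was not called at 4, 6 or 12 h (adjusted p = 0.29, 0.76 and 0.56).

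After 1 day of auxin 2-cell-stage genes were above untreated cells. Zscan4c, a telomere-associated gene of the 2-cell embryo, rose to 555 ± 95.5 from 173 ± 78.9, Zscan4f to 952 ± 208 from 235 ± 127 and the deubiquitinase gene Usp17lb to 119.9 ± 0.135 from 25.2 ± 6.96. Of 22 members 19 rose and 1 fell, or 20 and 1 adjusted over the list alone. The 2-cell median was 2.08, above 0 in both 1 day libraries (camera adjusted p = 1.2e-07, and adjusted p = 0.28 with an estimated correlation). It was 1.34 without untreated replicate 2. These genes belong to families of near-identical copies, so reads may have been divided between copies. Mdm2 was at 7985 ± 1271, Cdkn1a at 5456 ± 411 and Plk2 at 5024 ± 336. Of 39 p53 targets 31 rose, or 33 adjusted over the list alone (median 1.22, camera adjusted p = 1.5e-20, and adjusted p = 0.031 with an estimated correlation).

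Genes of DNA replication and sterol synthesis and targets of ATF4 fell at 1 day. Pcna, the replication clamp gene, fell to 5360.1 ± 185 from 11110.0 ± 48.8 and Ccne1, a cyclin E gene, to 1593 ± 214 from 3937 ± 287. Of 52 G1/S and replication genes 39 fell, or 42 adjusted over the list alone (median -0.53, or -0.35 without 1 day replicate 2; camera adjusted p = 3.3e-15, and adjusted p = 0.18 with an estimated correlation). The sterol gene Idi1 fell to 916 ± 172 from 3017 ± 399.8, and 19 of 25 sterol genes fell, or 22 adjusted over the list alone (median -0.65, camera adjusted p = 2.9e-11, and adjusted p = 0.010 with an estimated correlation). Of the ATF4 targets 24 fell and 4 rose, or 25 and 5 adjusted over the list alone (median -0.91, camera adjusted p = 1.8e-09, and adjusted p = 0.087 with an estimated correlation). Phgdh, the first enzyme gene of serine synthesis, went to 1058 ± 48.7 from 3763 ± 229.6 and Ddit4 rose to 1802 ± 31.3. Small-subunit genes had 35 members lower and 2 higher, or 40 and 2 adjusted over the list alone (median -0.28, camera adjusted p = 3.9e-08, and adjusted p = 0.24 with an estimated correlation). Large-subunit genes had 30 lower and 1 higher, or 32 and 1 adjusted over the list alone (median -0.28, camera adjusted p = 1.4e-08, and adjusted p = 0.15 with an estimated correlation). Nolc1, a nucleolar phosphoprotein gene, fell to 3186 ± 186 from 5948 ± 317.

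Pluripotency genes at 1 day went both ways, 9 higher and 8 lower of 32, or 10 and 9 adjusted over the list alone (median 0.13, camera adjusted p = 0.71). Lin28a, a translation regulator of stem cells, fell to 1075 ± 88.4 from 3276 ± 680.4 and Utf1 to 1453 ± 119.9, and Pou5f1 was lower at 17707 ± 1986 (log2 change -0.37, limma adjusted p = 0.0018). Klf4 was higher at 4841 ± 749.8 against 2647 ± 1036 (log2 change 0.92, limma adjusted p = 0.0017), with a change of 0.51 without untreated replicate 2. With the 2 groups fitted alone the calls of Pou5f1 (adjusted p = 0.15) and Klf4 (0.059) ended. Among 22 formative and primed epiblast genes 12 fell and 1 rose, or 13 and 2 adjusted over the list alone (median -0.81, or -0.37 without untreated replicate 2; camera adjusted p = 0.00059, and adjusted p = 0.13 with an estimated correlation). Etv4, an ETS factor gene downstream of FGF, was at 405 ± 101 against 2056 ± 525 and the DNA methyltransferase gene Dnmt3b at 1453 ± 85.5 against 2993 ± 369. Among the largest rises were those of Anxa8 (385 ± 64.6), Matn1, a cartilage matrix gene (356 ± 89.6 from 26.2 ± 29.8; log2 change 4.36, or 2.87 without untreated replicate 2), Ms4a10 (272 ± 45.6 from 14.5 ± 2.30) and the peptide transporter gene Tap1 (321 ± 32.5 from 20.99 ± 3.82). Falls were largest for genes such as Myrf, a membrane-bound transcription factor gene (15.3 ± 1.16 from 523 ± 339.9), Chac1 (7.45 ± 1.49), Aire (14.7 ± 6.75 from 275 ± 138), the stress gene Nupr1 (15.4 ± 10.3 from 246 ± 35.9) and Spry4 (44.8 ± 11.1).

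Counted over all genes, 2125 were higher and 2359 lower at 1 day, 818 and 457 of them by at least 2-fold. With the untreated and 1 day libraries fitted alone the counts were 682 and 537. With library weights, chosen after the data were seen, they were 873 and 1001, and in a fit of the libraries outside 2 to 12 h, also chosen then, the lower count was 1481.

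After 2 days of auxin the 2-cell-stage genes stood highest. Zscan4c (ENSMUSG00000054272, chromosome 7, 11005745 to 11010547) was at 1216 ± 120.2 against 173 ± 78.9 untreated, Zscan4f at 1751 ± 112, Zscan4b at 725 ± 65.6 against 90.4 ± 35.7 and Usp17lb at 212 ± 2.57. Of 22 members 21 rose, also adjusted over the list alone, and the median was 2.93, above 2 in both 2 day libraries (camera adjusted p = 6.8e-10, and adjusted p = 0.22 with an estimated correlation). Dppa3 (STELLA), a maternal-effect gene of naive cells, rose to 252 ± 5.26 from 34.4 ± 28.5 (log2 change 3.12, limma adjusted p = 0.0011). The p53 targets stayed high: Cdkn1a was at 5489 ± 4.00 (log2 change 1.84, adjusted p = 4.6e-09), Mdm2 at 7672 ± 68.2, Plk2 at 4932 ± 170.4 and Perp, a desmosome and cell death gene, at 1338 ± 36.3 against 108 ± 38.9.

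In the p53 list 31 of 39 genes rose, or 32 with 1 lower adjusted over the list alone (median 1.09, camera adjusted p = 1.7e-14, and adjusted p = 0.0501 with an estimated correlation). Trp53 mRNA was at 10852 ± 336 against 8800.2 ± 605 (log2 change 0.30, limma adjusted p = 0.0016). Cell cycle lists fell. Of 52 G1/S and replication genes 48 were lower, or 49 adjusted over the list alone (median -0.87, camera adjusted p = 1.5e-20, and adjusted p = 0.14 with an estimated correlation). Of 50 G2/M genes 44 were lower and 2 higher, the same adjusted over the list alone (median -0.76, camera adjusted p = 4.5e-16, and adjusted p = 0.087 with an estimated correlation). Pcna was at 3905 ± 82.6 against 11110.0 ± 48.8, Uhrf1, a maintenance methylation gene, at 2584 ± 82.3 against 8996 ± 512. The mitotic genes Ccnb1 and Plk1 were at 3173 ± 120.5 and 1774 ± 177 against 6363 ± 321 and 4098 ± 448. Psrc1, a spindle gene that is also in the p53 list, rose to 5928 ± 0.00637 from 2793 ± 139.5.

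Ribosome biogenesis genes remained low at 2 days. Of 62 small-subunit genes 45 fell and 1 rose, or 46 and 2 adjusted over the list alone (median -0.36, camera adjusted p = 1.4e-08, and adjusted p = 0.22 with an estimated correlation). Of 56 large-subunit genes 40 fell and 2 rose, the same adjusted over the list alone (median -0.38, camera adjusted p = 3.5e-09, and adjusted p = 0.14 with an estimated correlation). Lyar was at 1524 ± 28.7 against 3678 ± 53.3, and Nolc1 at 2782 ± 148 against 5948 ± 317. Tcof1, the treacle gene, was at 4756 ± 95.7 against 8274 ± 583, and Bop1, a 28S rRNA processing gene, at 2019.6 ± 48.0 against 3297 ± 216. RNA polymerase I and III genes were not called (median -0.16, camera adjusted p = 0.054), with 11 of 36 lower and 2 higher, the same adjusted over the list alone. ATF4 targets had 24 lower and 5 higher of 33, the same adjusted over the list alone (median -0.96, camera adjusted p = 4.4e-07, and adjusted p = 0.13 with an estimated correlation). Psat1 was at 2114 ± 33.3 against 8696 ± 523 and the asparaginyl-tRNA synthetase gene Nars at 2800.4 ± 42.2 against 7373 ± 261.

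The pluripotency list was not called at 2 days (median 0.21, camera adjusted p = 0.34): 14 of 32 genes rose and 10 fell, or 15 and 10 adjusted over the list alone. Pou5f1 was lower at 18280.2 ± 879 (log2 change -0.32, limma adjusted p = 0.0033), Zfp42 lower at 8799 ± 417 against 11639 ± 659.7 (-0.40, adjusted p = 9.9e-05), Lin28a lower at 854 ± 56.5 and Utf1 lower at 2169 ± 153. Klf4 was higher at 5421 ± 61.4 against 2647 ± 1036 (1.09, adjusted p = 3.0e-04, or 0.68 without untreated replicate 2), as were the adhesion genes Jam2 (5874 ± 153 against 3825 ± 83.5) and Pecam1 (2863 ± 103 against 1723 ± 7.59). Nanog was at 17203 ± 523 against 14829 ± 712 (0.21, adjusted p = 0.013). That call ended without untreated replicate 2 (0.081) or 2 day replicate 1 (0.095), with the 2 groups fitted alone (0.077) and in the fit of libraries outside 2 to 12 h (0.088). Sox2, at 8471 ± 27.2 against 9224 ± 468, and Esrrb, at 19014 ± 232 against 17124 ± 2896, did not pass. Epiblast genes of the formative and primed states had 10 of 22 lower and 3 higher, the same adjusted over the list alone (median -0.52, camera adjusted p = 0.047, and adjusted p = 0.30 with an estimated correlation), with Etv4 at 150.0 ± 7.98. The epiblast call ended without untreated replicate 2 (median -0.24, adjusted p = 0.18) or 2 day replicate 2 (0.059), with a mean of at least 50 required (0.19) and with the 2 groups fitted alone (0.087). It also ended in the fit of libraries outside 2 to 12 h (0.052) and with replicate as a block (0.0503), and without untreated replicate 1 the median was -0.80.

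Markers of other cell types were read at 2 days from lists fixed beforehand. Primitive endoderm genes rose, with 9 of 15 higher, also adjusted over the list alone (median 1.01, camera adjusted p = 0.0015, and adjusted p = 0.087 with an estimated correlation). The basement membrane genes Col4a1 and Col4a2 were at 3174 ± 232 and 1425 ± 16.6 against 498 ± 201 and 270.4 ± 167, and the collagen chaperone gene Serpinh1 at 1258 ± 46.0 against 375 ± 9.67. Trophoblast genes (median 0.54, camera adjusted p = 0.091; 7 of 18 higher, 3 lower), mesoderm genes (0.41, 0.40; 3 of 12 higher), fibroblast genes (0.70, 0.32; 5 of 11 higher, 1 lower) and germline genes (0.28, 0.35; 4 of 19 higher, 3 lower) were not called. Adjusted over the list alone these counts were the same except that 2 germline genes were lower. Neuroectoderm genes had a median of -0.02, a mean of 0.29 and a test that pointed up (camera adjusted p = 0.48), with 3 of 11 higher and 4 lower, the same adjusted over the list alone. Sox21, a neural SOX factor gene, rose to 1174 ± 15.2 from 216 ± 3.56 and Neurod1 to 179 ± 15.5. Interferon response genes were not called (median -0.06, camera adjusted p = 0.57), with 5 of 15 lower and 2 higher, or 5 and 3 adjusted over the list alone.

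Cyp1a1 and Cyp1b1 were at 781 ± 45.2 and 159.6 ± 8.96 at 2 days, and 5 of 9 aryl hydrocarbon receptor targets rose and 1 fell, or 6 and 2 adjusted over the list alone. Their median was 0.78 (camera adjusted p = 0.037, and adjusted p = 0.16 with an estimated correlation). The receptor call ended without untreated replicate 1 (median 0.37, adjusted p = 0.094), with a mean of at least 50 required (median 0.48, 0.073) and with the 2 groups fitted alone (0.053). The largest rises at 2 days included Matn1 (492 ± 16.2 from 26.2 ± 29.8), Serpine2, a protease inhibitor gene (1935 ± 64.3 from 103 ± 40.4; log2 change 4.28) and Plbd1 (206 ± 4.05 from 11.5 ± 1.14). Also high were Ptgs2, the inducible cyclooxygenase gene (187 ± 5.92 from 11.7 ± 0.724), Cpz (309 ± 11.2), Tap1 (305 ± 62.4), Tmem30b (97.9 ± 4.09 from 6.26 ± 1.67) and the sarcomere gene Myom2 (222 ± 17.9 from 15.6 ± 1.13). Cacna1s and Snx20 were also among them, but their log2 changes fell from 4.73 and 4.48 to 2.30 and 2.48 without untreated replicate 2, and the Cacna1s call ended (limma adjusted p = 0.056). The largest falls included Myrf (7.28 ± 2.28 from 523 ± 339.9; log2 change -5.84), Chac1 (5.05 ± 2.09 from 217 ± 139.8) and Spry4 (27.0 ± 9.47 from 666 ± 116). Also low were the lactate transporter gene Slc16a3 (31.1 ± 10.8 from 666 ± 434), Nkx1-2 (14.6 ± 8.10 from 264 ± 125), Aire (16.4 ± 1.61), Nupr1 (16.98 ± 9.04), Etv4 and Ptgs1 (19.2 ± 0.623 from 201 ± 11.4).

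At 2 days, 2806 genes were higher and 3179 lower, 1199 and 677 by at least 2-fold. Over the auxin times the limma F-test called 8702 of 13355 genes. First calls against untreated were 687 higher and 571 lower at 4 h, 488 and 557 at 6 h, 808 and 901 at 12 h, 916 and 1022 at 1 day, and 710 and 822 at 2 days. Both may include a batch of the 2 to 12 h libraries.

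**Figure D2:**
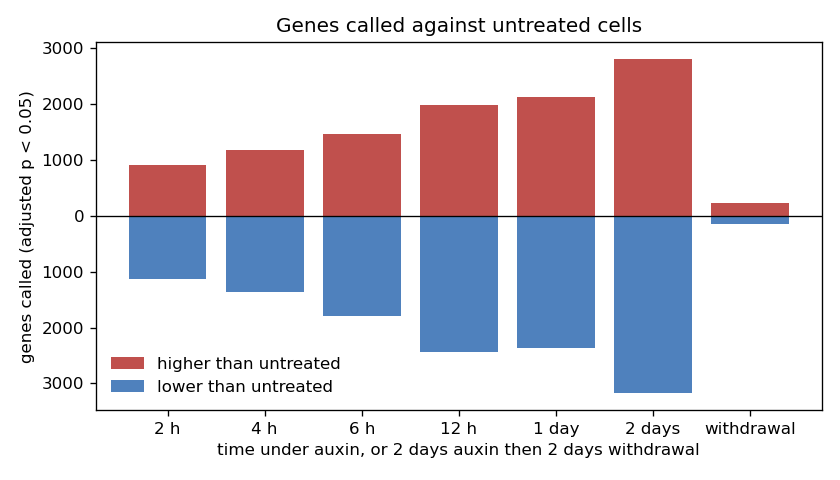
Number of genes called against untreated cells by limma (y axis, higher as bars above 0 and lower as bars below 0) at each time under auxin and after withdrawal (x axis). Counts go from 902 higher and 1128 lower at 2 h to 2806 and 3179 at 2 days, and are 230 and 143 after withdrawal.

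Of the genes called at 1 day and at 2 days, 1812 were higher in both and 1996 lower in both, with 4 higher at 1 day and lower at 2 days and 1 the reverse. Independent lists of these sizes would share 446 and 562. In 100 simulations of unchanged groups against the same untreated libraries at most 2 genes were called at 1 day, so their shared counts of 0 and 0 say nothing about these overlaps. The fold changes had a covariance over genes of 0.54, against 0.042 when simulated, and a correlation of 0.87, against 0.50. Part of the shared counts may come from the shared controls. With 1 untreated library for each comparison, an alternative chosen after the data were seen, the shared counts were 1255 and 1535 or, with the libraries exchanged, 1345 and 1499, against 353 and 447 or 387 and 472 for independent lists. The covariance was then 0.43 or 0.45. With the 2 groups of each comparison fitted alone the shared counts were 658 and 511, and with library weights 844 and 952.

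**Figure D3:**
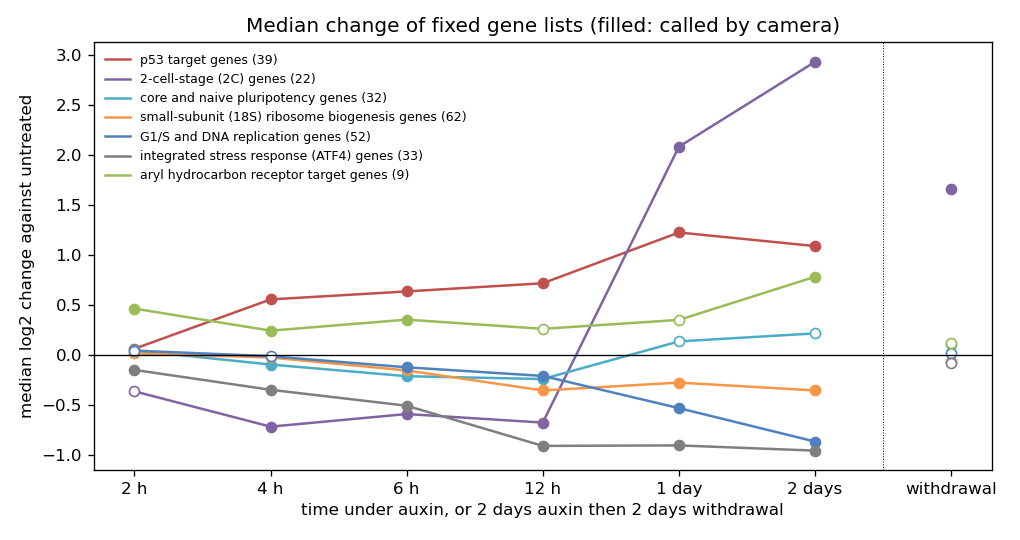
Median log2 change against untreated (y axis) of 7 gene lists fixed before the data were examined, at each time under auxin and after withdrawal (x axis), with the number of tested genes in the legend and filled points where camera called the list. The 2-cell median goes from -0.68 at 12 h to 2.93 at 2 days and is 1.65 after withdrawal, while the p53 target median goes from 0.06 at 2 h to 1.22 at 1 day and is -0.07 after withdrawal.

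After withdrawal p53 targets and Cyp1a1 were back near untreated levels, and some 2-cell-stage and growth-response genes were above them. Mdm2 was at 2320.0 ± 143 against 2454 ± 29.5, Cdkn1a at 1435 ± 98.5 against 1530.1 ± 10.1, Cyp1a1 at 56.7 ± 25.9 against 62.1 ± 17.4 and Pou5f1 at 25019.9 ± 328 against 22755 ± 588, none of which passed the test. Zscan4f was higher than untreated at 757 ± 2.28 against 235 ± 127 and Zscan4c at 456 ± 55.8 against 173 ± 78.9 (log2 change 1.47, limma adjusted p = 0.0085, but 0.058 and 0.093 without withdrawal replicate 1 and 2). Fos, a component of AP-1, was higher at 597 ± 28.7 against 121 ± 65.4, Dio3, a thyroid hormone deiodinase gene, at 361 ± 13.1 against 61.0 ± 21.3, and Ndrg1, a hypoxia-responsive gene, at 475 ± 47.8 against 154 ± 36.8. Lin28a at 1783 ± 26.6 against 3276 ± 680.4, Phgdh at 2389.9 ± 62.8 against 3763 ± 229.6 and the muscle myosin light chain gene Mylpf at 1021 ± 96.5 against 3129 ± 620.1 were lower. In the fit of libraries outside 2 to 12 h the calls of Zscan4f (limma adjusted p = 0.081), Zscan4c (0.099), Fos (0.079), Lin28a (0.077) and Phgdh (0.061) ended, and those of Dio3, Ndrg1 and Mylpf held. With the untreated and withdrawal libraries fitted alone all 8 of these calls ended (adjusted p of 0.15 to 0.26).

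The 2-cell list had 9 of 22 members higher after withdrawal, or 19 adjusted over the list alone, and a median of 1.65, above 1.5 in both withdrawal libraries (camera adjusted p = 3.1e-16, and adjusted p = 0.13 with an estimated correlation). The median was 0.92 without untreated replicate 2 and 2.39 without untreated replicate 1, and the list was called in both cases. Of 27 immediate early genes 7 were higher and 1 lower, or 8 and 2 adjusted over the list alone (median 0.31, camera adjusted p = 4.1e-06, and adjusted p = 0.11 with an estimated correlation). Egr1, a growth factor response gene, was at 2259.7 ± 424 against 23.2 ± 10.02 (log2 change 6.59, limma adjusted p = 0.0072). The Egr1 call ended without withdrawal replicate 1 (0.071) or 2 (0.057) and in the fit of libraries outside 2 to 12 h (0.10). Glycolysis and hypoxia genes had 11 of 30 higher, or 15 adjusted over the list alone (median 0.24, camera adjusted p = 1.3e-12, and adjusted p = 0.041 with an estimated correlation). The p53 list was not called (median -0.07, camera adjusted p = 0.11; 4 lower, or 10 lower and 3 higher adjusted over the list alone), nor were the pluripotency list (0.11, 0.086), the ATF4 list (-0.08, 0.062) and the receptor list (0.12, 0.19), although its member Cyp2s1 was higher at 128 ± 26.7 against 60.7 ± 1.26 (limma adjusted p = 0.046, but 0.057 to 0.27 without any 1 of the 4 libraries, 0.31 with the 2 groups fitted alone, 0.27 in the fit of libraries outside 2 to 12 h and 0.13 with library weights). G1/S and replication genes had a median of 0.01, a mean of 0.0021 and a test that pointed down (adjusted p = 0.89). Small-subunit and large-subunit genes had medians of -0.07 each (camera adjusted p = 0.022 and 0.015, and adjusted p = 0.59 and 0.46 with an estimated correlation). Without untreated replicate 1 these medians were -0.01 and -0.02 (adjusted p = 0.64 and 0.29) and without withdrawal replicate 2 -0.03 and -0.04 (0.27 and 0.21), which ended both calls, as did fry (0.21 and 0.12).

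In this comparison 230 genes were higher and 143 lower than untreated, 93 and 38 of them by at least 2-fold, and 2308 genes had an unadjusted p below 0.05. The counts depended on single libraries and on the fit. They were 721 and 385 without untreated replicate 1, 35 and 32 without withdrawal replicate 1, and 45 and 24 without withdrawal replicate 2. They were 10 and 5 in the fit of libraries outside 2 to 12 h, and 90 and 40 with library weights. They were 1 and 0 when limma fitted the untreated and withdrawal libraries alone, where 757 and 697 genes had an unadjusted p below 0.05.

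Against the end of auxin, p53 targets were lower in withdrawal cells and sterol synthesis genes higher, also with an estimated correlation. Cell cycle and ribosome biogenesis lists were called higher too, but these calls were lost with an estimated correlation (adjusted p of 0.087 to 0.28). Cdkn1a went from 5489 ± 4.00 at 2 days to 1435 ± 98.5, Mdm2 from 7672 ± 68.2 to 2320.0 ± 143, Ccng1 from 11324 ± 379 to 3689 ± 307, and Cyp1a1 from 781 ± 45.2 to 56.7 ± 25.9. Pcna rose from 3905 ± 82.6 to 11169.9 ± 443, Uhrf1 from 2584 ± 82.3 to 8799.9 ± 13.3 and the chromosomal passenger kinase gene Aurkb from 782 ± 19.6 to 1614 ± 61.8. Nolc1 rose to 5631 ± 114 from 2782 ± 148, Lyar to 3037 ± 185 from 1524 ± 28.7, Psat1 to 6190.1 ± 228 from 2114 ± 33.3 and Idi1 to 2863 ± 77.5 from 682 ± 22.7. Ddx10 mRNA rose to 1596 ± 139 from 1019 ± 30.5 (log2 change 0.64, limma adjusted p = 3.4e-04).

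Of 39 p53 targets 31 were lower than at 2 days and 1 higher, also adjusted over the list alone (median -1.18, camera adjusted p = 4.5e-16, and adjusted p = 0.044 with an estimated correlation). In the G1/S list 48 of 52 rose, or 49 adjusted over the list alone (median 0.89, camera adjusted p = 3.4e-22, and adjusted p = 0.13 with an estimated correlation). In the G2/M list 43 of 50 rose and 2 fell, or 44 and 3 adjusted over the list alone (median 0.70, camera adjusted p = 5.2e-16, and adjusted p = 0.087 with an estimated correlation). Small-subunit genes rose, 40 of 62 with 2 lower, or 41 and 3 adjusted over the list alone (median 0.33, camera adjusted p = 4.6e-07, and adjusted p = 0.28 with an estimated correlation). Large-subunit genes rose as well, 39 of 56 with 2 lower, or 40 and 2 adjusted over the list alone (median 0.32, camera adjusted p = 1.2e-07, and adjusted p = 0.16 with an estimated correlation). Sterol genes rose in 20 of 25 cases, or 21 adjusted over the list alone (median 0.64, camera adjusted p = 7.7e-09, and adjusted p = 0.013 with an estimated correlation). ATF4 targets rose in 23 of 33 cases with 3 lower, or 24 and 4 adjusted over the list alone (median 0.84, camera adjusted p = 5.3e-07, and adjusted p = 0.13 with an estimated correlation). The 2-cell list was lower than at 2 days, with 12 of 22 members down, also adjusted over the list alone (median -1.29, camera adjusted p = 0.00061, and adjusted p = 0.45 with an estimated correlation).

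Primitive endoderm genes fell, 8 of 15 with 1 higher, also adjusted over the list alone (median -0.94, camera adjusted p = 0.0039, and adjusted p = 0.11 with an estimated correlation), with Col4a1 at 944 ± 27.2 and Serpinh1 at 202 ± 13.0. Trophoblast genes had 7 of 18 lower and 3 higher, also adjusted over the list alone (median -0.80, camera adjusted p = 0.028, and adjusted p = 0.34 with an estimated correlation), with Tfap2c at 394 ± 0.0167 against 1711 ± 90.1. Formative and primed epiblast genes had 10 of 22 higher and 3 lower, also adjusted over the list alone (median 0.77, camera adjusted p = 0.035, and adjusted p = 0.30 with an estimated correlation). With a mean of at least 50 required the calls of the trophoblast (adjusted p = 0.17) and epiblast (0.15) lists ended, and with the length and GC trend removed that of the trophoblast list (0.070). Pou5f1 rose to 25019.9 ± 328 from 18280.2 ± 879 (log2 change 0.45, limma adjusted p = 2.7e-04) and Utf1 to 5196 ± 52.8 from 2169 ± 153. The pluripotency list had 11 members higher and 11 lower, or 12 and 12 adjusted over the list alone (median -0.07, camera adjusted p = 0.86). Large rises were seen for Slc16a3 (1299 ± 93.5 from 31.1 ± 10.8), Chac1 (190.0 ± 9.90), Myrf (253 ± 19.4) and Aire (323 ± 40.03). Large falls were seen for the scaffold gene Ahnak2 (33.8 ± 16.04 from 712 ± 74.4), Cpz (14.6 ± 6.93), Serpine2 (113 ± 19.3), Plbd1 (12.0 ± 1.79) and Ms4a10 (12.4 ± 5.38 from 206 ± 20.5).

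Between withdrawal and 2 days 2960 genes were higher and 2556 lower, 628 and 990 of them by at least 2-fold. Of the 2806 genes higher at 2 days than in untreated cells, 1967 (70.1%) fell after withdrawal, and their median log2 change against untreated went from 0.85 to 0.14. Of the 3179 lower genes, 2483 (78.1%) rose, with medians of -0.60 and -0.08. Genes called in the same direction against untreated at 2 days and after withdrawal numbered 156 higher and 78 lower, with 25 higher at 2 days and lower after withdrawal and 17 the reverse. Independent lists would share 48.3 and 34.04 genes, and simulated unchanged groups, with at most 1 gene called at 2 days, shared 0 and 0, which says nothing about the counts. The covariance of the fold changes was 0.15, against 0.042 simulated, and the correlation 0.40, against 0.50. Part of the shared counts and of the covariance may come from the shared controls. With 1 untreated library for each comparison the covariance was 0.098 or, with the libraries exchanged, 0.018, and the shared counts were 336 and 137 or 97 and 66, against 123 and 81.2 or 42.9 and 39.6 for independent lists. Without untreated replicate 1 the shared counts were 581 and 248, in the fit of libraries outside 2 to 12 h 7 and 3, and with 2 groups fitted alone 1 and 0.

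**Figure D4:**
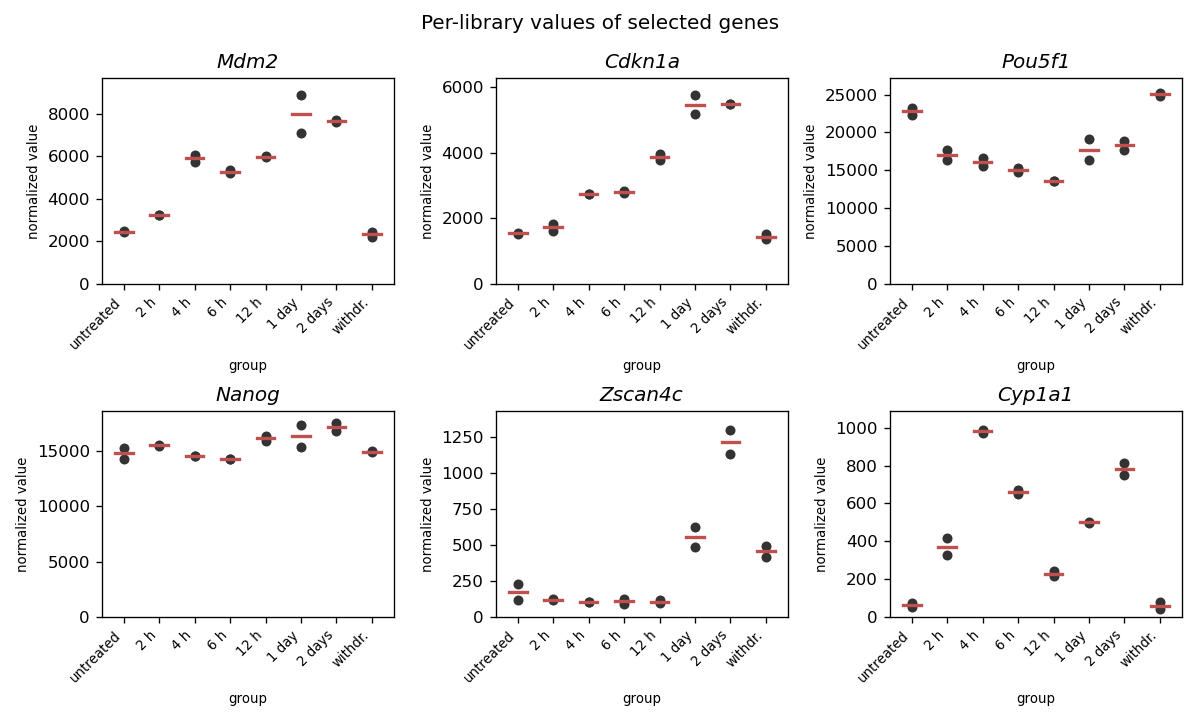
Normalized values (y axis) of Mdm2, Cdkn1a, Pou5f1, Nanog, Zscan4c and Cyp1a1 in each library (points) by group (x axis), with red bars at the mean of the 2 libraries. Cdkn1a goes from 1530.1 in untreated cells to 5489 at 2 days and 1435 after withdrawal, and Zscan4c from 173 to 1216 and 456.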

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

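Of the tests in this part, the correlation with transcript length, the count of genes that part the libraries, the comparisons with 2 h, and those on aryl hydrocarbon receptor targets and on reversal after withdrawal were chosen only after the result was seen.

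The lists and genes below were picked for calls in opposite directions against untreated at 2 times, so testing the difference adds no support. The 2-cell list differed by 3.59 between 2 days and 12 h (camera adjusted p = 2.8e-14; medians of 2.93 and -0.68 against untreated). The G2/M list differed by -0.83 between 2 days and 4 h (adjusted p = 1.3e-20; -0.76 and 0.10), where the rise at 4 h was no longer called without untreated replicate 2 (adjusted p = 0.079), nor with an estimated correlation (adjusted p = 0.44 with an estimated correlation). The sterol list differed by -0.78 between 1 day and 4 h (adjusted p = 5.0e-15; -0.65 and 0.29). By limma, Ddx10 differed by -0.93 between 2 days and 2 h (adjusted p = 1.1e-05; -0.53 and 0.40), and Trp53 by 0.56 between 2 days and 12 h (adjusted p = 2.8e-05; 0.30 and -0.25). Dppa3 differed by 5.09 between 2 days and 6 h (adjusted p = 2.9e-05; 3.12 and -1.97), and Zscan4d by 3.55 (adjusted p = 4.8e-06; 2.41 and -1.15). All 7 of these differences cross the split between the libraries of 2 to 12 h and the others. With an estimated correlation the fall of the G2/M list at 2 days (adjusted p = 0.087) and both calls of the 2-cell list (0.61 at 12 h and 0.22 at 2 days) ended too, and those of the sterol list held. The early calls ended without untreated replicate 1 for the 2-cell list at 12 h (median -0.01, adjusted p = 0.83), Ddx10 at 2 h (limma adjusted p = 0.089), Trp53 at 12 h (0.061), and Dppa3 and Zscan4d at 6 h (log2 changes of -1.03 and -0.39, 0.28 and 0.26).

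The libraries of 2, 4, 6 and 12 h stood apart from the other 8 at 1015 genes. A bias over transcript length shared by these libraries may be part of this, since the log2 change at 2 h had a Spearman correlation of 0.22 with length, with values of 0.21 to 0.24 at 4 to 12 h and -0.01 to 0.09 for the other groups against untreated. Length and GC content are not the whole of it: with that trend removed from each library 1867 genes were still called at 2 h, against 2030 before. A library batch that the labels do not record and the early response to auxin cannot be told apart, because the same libraries would share both and the 1015 genes were picked for this division. The p53 and ribosome biogenesis changes at 12 h do not rest on the split alone, as they were also called against 2 h. In that separate fit the adjusted p with an estimated correlation was 0.022, or 0.025 to 0.027 with the length and GC trend removed. The pluripotency call was then lost at 12 h (0.059) and held at 4 and 6 h (0.022 each).

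Targets of the aryl hydrocarbon receptor were called higher at 2, 4 and 6 h and 2 days, each call lost with an estimated correlation (adjusted p of 0.055 to 0.16), but not at 12 h (median 0.26, adjusted p = 0.080) or 1 day (0.35, 0.081). The library split as their cause is argued against by the 2 day libraries, which lie on the untreated side of it and had a list median of 0.78, although that call ended without untreated replicate 1 (adjusted p = 0.094). Whether auxin, an indole, acts on the receptor apart from DDX10 loss cannot be told apart from an effect of DDX10 loss: the list median was 0.46 at 2 h, and libraries with auxin and no degron were not analysed here.

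Genes of the 2-cell stage were above untreated after withdrawal. Reads shared between Zscan4 copies are argued against as the whole cause, because the 18 list members outside that family had a median of 1.69 and all 18 were above 0.5, although some of these are copies of other families. A baseline set by 1 untreated library is argued against by a narrow margin: the median was 0.92 without untreated replicate 2 and 2.39 without replicate 1, against 1.65 with both (adjusted p = 0.13 with an estimated correlation). Incomplete reversal of an effect of auxin may be the cause, as the list was lower after withdrawal than at 2 days (median -1.29, and adjusted p = 0.45 with an estimated correlation), but a drift over the days in culture cannot be told apart from it without untreated cells kept as long.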

How the results depend on the processing

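Library weights, the fit of libraries outside 2 to 12 h, removal of the length and GC trend, the 2 h baseline with and without that trend, and the divided controls were chosen only after the data were seen. The counts of calls below are given as higher and lower.

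With the 2 compared groups fitted alone the counts were 138 and 270 at 2 h and 337 and 394 at 4 h. They were 587 and 824 at 6 h, 1183 higher at 12 h, and 682 and 537 at 1 day. After withdrawal they were 1 and 0 against untreated, but rose to 3399 and 3106 against 2 days. Overlaps were 658 and 511 for 1 day with 2 days, and 1 and 0 for 2 days with withdrawal. Fewer samples are thus not the whole cause. With library weights the counts were 462 and 648 at 2 h, 710 and 794 at 4 h, 958 higher at 6 h, 873 and 1001 at 1 day, and 90 and 40 after withdrawal, and the overlaps were 844 and 952, and 63 and 29. The cause was not tested. In the fit of libraries outside 2 to 12 h, which has fewer samples, 1481 genes were lower at 1 day and 10 and 5 differed after withdrawal, with overlaps of 1271 lower, and of 7 and 3. With an estimated correlation 8 of the 87 list calls held, and the cause was not tested.

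Leaving out 1 library at a time gave ranges of 166 to 923 higher and 335 to 1369 lower at 2 h, 421 to 1234 and 505 to 1479 at 4 h, 654 to 1489 and 953 to 1842 at 6 h, 1095 to 1907 and 1736 to 2568 at 12 h, 1676 to 2279 and 1990 to 2605 at 1 day, and 2006 to 2814 and 2460 to 2988 at 2 days. After withdrawal the ranges were 35 to 721 and 24 to 385 against untreated, and 2136 to 2291 and 1740 to 1821 against 2 days. The F-test count was 7667 to 9349. Overlaps were counted only without untreated replicate 1 or 2, and were 1442 to 1995 and 1739 to 1904 for 1 day with 2 days, and 125 to 581 and 86 to 248 for 2 days with withdrawal. Without untreated replicate 1 the 2-cell list at 6 h had a median of 0.0156 in place of -0.59 (adjusted p = 0.84), and without untreated replicate 2 a median of -1.17 (adjusted p = 1.4e-06).

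The counts of calls stayed within 1.5 times those reported with pseudocounts of 0.5 and 5, with no filter, with a mean of at least 50, with both rescalings, with replicate as a block and with the length and GC trend removed. Deviations of replicates with the same number were nearly uncorrelated between groups (-0.061 to 0.066 over 28 pairs of groups), so replicates were not treated as pairs. Of 738 calls of named genes, 473 were kept under every alternative run for them, 265 were lost under at least 1, and none changed sign. Of 87 list calls 8 were kept under every alternative, 79 were lost under at least 1, the test changed direction for 1, and the median changed sign for 2. Tests on whole reads with edgeR and DESeq2 were planned and not run, because whole reads could not be recovered for all genes. In simulated data 40.9% of genes changed by a log2 value of 0.5 were called, and depth was not varied there.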

Other observations

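The tests in this part were planned, and the genes Socs3 and Xaf1 were chosen only after their values were seen.

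Glycolysis, sterol, chaperone and immediate early genes changed as well. Glycolysis and hypoxia genes fell at 2 days, 20 of 30 with 2 higher, or 21 and 3 adjusted over the list alone (median -0.46, camera adjusted p = 7.3e-06, and adjusted p = 0.11 with an estimated correlation). The triose phosphate isomerase gene Tpi1 was at 1148 ± 3.79 against 4832 ± 587, the lactate dehydrogenase gene Ldha at 5882 ± 347 against 20508 ± 2839.9 and the enolase gene Eno1 at 16294 ± 1017 against 45353 ± 3714. After withdrawal 23 of 30 rose against 2 days and 1 fell, or 24 and 1 adjusted over the list alone (median 0.87, camera adjusted p = 3.2e-12, and adjusted p = 0.041 with an estimated correlation), with Tpi1 at 6537 ± 46.9 and Ldha at 20874 ± 615. Sterol synthesis genes were lower at 2 days, 18 of 25, the same adjusted over the list alone (median -0.48, camera adjusted p = 5.3e-07, and adjusted p = 0.022 with an estimated correlation). Their member Idi1 was at 682 ± 22.7 against 3017 ± 399.8.

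Heat shock and chaperone genes fell at 2 days, 17 of 28 with 2 higher, or 17 and 3 adjusted over the list alone (median -0.42, camera adjusted p = 0.00042, and adjusted p = 0.20 with an estimated correlation). The mitochondrial chaperone gene Hspd1 was at 15557 ± 76.0 against 28161 ± 65.0 and the cochaperone gene Stip1 at 6482 ± 122 against 11273 ± 57.2. Of 27 immediate early genes 13 rose and 4 fell at 2 days, the same adjusted over the list alone (median 0.64, camera adjusted p = 0.0070, and adjusted p = 0.27 with an estimated correlation). Btg2, which is also a p53 target, rose to 2601 ± 49.3 from 529 ± 176 and the phosphatase gene Dusp1 to 1329 ± 23.5 from 595 ± 56.3, while Myc fell to 56.8 ± 14.5 from 436 ± 2.11 (limma adjusted p = 4.2e-08).

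Egr1 was at 30.3 and 16.2 in the untreated libraries, 611 and 16.4 at 1 day, 212 and 82.4 at 2 days, and 2559 and 1960.1 after withdrawal. Socs3 was at 58.1 in untreated replicate 2 and at 738 to 1465 in the other 15 libraries, and Xaf1 at 107 and 542 to 975. Klf4 was at 3380 in untreated replicate 1 and 1915 in replicate 2.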
